A study of Mus musculus with 6 samples.

How the data were processed

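RNA of LSK cells sorted from the bone marrow of mice 10 to 14 weeks old was measured on 6 Affymetrix expression arrays, 2 for each of CD34-Flt3-, CD34+Flt3- and CD34+Flt3hi cells. Per the labels the cells were sorted into lysis buffer, the RNA was purified with a micro kit and amplified in 2 rounds of in vitro transcription, and biotin-labelled RNA was hybridised. The authors' processing notes name RMA, the robust multi-array average, without a version and without saying which arrays were processed together. The deposited values are taken here as linear RMA signal intensities, an inference from their range, since they run from 6.50 to 24174 and RMA usually ends on a log2 scale. Their log2 was taken for every test. Array data have no depth, and the number of arrays limits the precision.

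The value table held 45101 probe sets. Of these 64 were manufacturer's controls, and of the others 34945 carried 1 gene symbol, 932 several and 9160 none. Symbols were updated by gene identifier, matched for 99.4% of the identifiers, and no coordinates were used. Genes with several probe sets (9010 of 18193) were read from the probe set with the highest mean over all arrays. Probe sets with several symbols were left out, and those with none were tested separately. Background was the 90th percentile over the 6 arrays of 27 bacterial control probe sets that were not spiked, a log2 of 4.50 or 22.6 in linear units. Where the mean of a group lay below it, values of that group below background were set to it, and the fold is given as "at least".

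The group means of all 6 arrays were fitted with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the data.table package), with empirical Bayes moderation and an intensity trend. The fit had 3 residual and 6.86 prior degrees of freedom and a median residual SD of 0.24. The comparisons were CD34+Flt3- minus CD34-Flt3-, CD34+Flt3hi minus CD34+Flt3- and CD34+Flt3hi minus CD34-Flt3-. The difference of the first of these from the next and a moderated F over the 3 groups were also tested. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none is reported.

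Before the data were examined, 27 gene lists were fixed. They covered the sort antigens, stem-cell-associated genes, megakaryocyte and erythroid, lymphoid, and granulocyte and monocyte genes, S phase, G2 and M phase, cell cycle inhibitors and D cyclins, Hox genes and cofactors, cytokine and growth factor receptors, adhesion and homing, oxidative phosphorylation, glycolysis and hypoxia, cytosolic ribosomal proteins, ribosome biogenesis and Myc targets, MHC class II, interferon response, immediate early and stress genes, sex-linked genes, and markers of mature erythroid, neutrophil and monocyte, B lineage, T and NK lineage, mast cell, basophil and eosinophil, dendritic, endothelial, and stromal and bone lineage cells. The 26 lists with at least 4 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, and the 78 tests were adjusted together. With an estimated correlation no list passed, and 2, 4 and 6 lists had an unadjusted p under 0.05 in the 3 comparisons. Counts adjusted over the list alone use the same limma p-values.

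The comparisons, tests, lists, most alternatives and the rule for named genes were set before the data were examined. The rule named the 8 largest rises and 8 largest falls of each comparison among genes past the threshold whose arrays did not overlap between the groups, passing over predicted genes, and the sort antigens. List examples were up to 4 members with the smallest adjusted p, or up to 2 as values where none passed. Alternatives were the title code as a fixed or a random block, no intensity trend, a robust prior, array weights, quantile normalization again, median centring, leaving out genes dimmer than the median gene, the mean of all probe sets, leaving out probe sets with an x or s suffix, all probe sets singly, only the 4 arrays compared, an adjusted p under 0.10, a 2-fold minimum, an estimated correlation and leaving out each array in turn. A block of code A against the other codes was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

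The pipeline was tested on simulated data, changes of known size added to random values with each gene's mean and residual SD. The random values were independent between genes and had the same SD in all groups. Changes of log2 1, 2 and 3 were recovered in 4.48%, 62.7% and 87.9% of genes for the first comparison, 14.9%, 76.1% and 95.5% for the next and 7.46%, 73.1% and 86.4% for the last. False calls made up 1.9%, 3.12% and 5.13% of the calls. In the real arrays the median SD between replicates was 0.24 in CD34-Flt3-, 0.18 in CD34+Flt3- and 0.13 in CD34+Flt3hi cells, and genes varied together. These rates may therefore not hold for the real data.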

Results

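Expression arrays were hybridised with RNA from LSK cells of adult mouse bone marrow, the lineage-negative cells positive for Sca1 and Kit among which blood stem cells and early multipotent progenitors are found. The cells had been sorted by the surface antigens CD34 and Flt3 into CD34-Flt3-, CD34+Flt3- and CD34+Flt3hi cells, and each group had 2 arrays. The series was made to look for expression changes between functionally distinct LSK subpopulations. Values were log2 intensities of 18193 genes, each read from its brightest probe set, and groups were compared with limma in a fit of all 6 arrays. The labels do not say whether the 2 arrays of a group came from separate mice or sorts. The p-values then measure only the spread between these arrays, which may be technical. The sample titles carry 3 codes of unstated meaning, called A, B and C here. Code A held replicate 2 of each group, code B held replicate 1 of the CD34+Flt3- and CD34+Flt3hi groups, and code C held replicate 1 of the CD34-Flt3- group. A fixed block of title codes therefore fits the code C array exactly. With it, comparisons with CD34-Flt3- cells and the difference of the steps rest on replicate 2 of that group alone. Differences within code A, and within code B where both groups had an array, rest on 1 array per group and stand beside the results as codes A and B.

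The median linear intensity was between 29.7 and 31.4 on each array. Background, the 90th percentile of 27 bacterial control probe sets, lay at a log2 of 4.50, and 26.7% of the genes had a mean below it. Across genes, which are not independent replicates, Pearson's r between the 2 arrays of a group was 0.969 for CD34-Flt3-, 0.981 for CD34+Flt3- and 0.990 for CD34+Flt3hi. The number of genes that differed over 2-fold between the 2 arrays was 1352, 476 and 112 in the same order. CD34-Flt3- replicate 1 was nearer to CD34+Flt3- replicate 1 (r of 0.971, 1142 genes over 2-fold) than to its own replicate. The first principal component held 50.2% of the variance and placed the CD34-Flt3- arrays at -48.7 and -47.7, the CD34+Flt3- arrays at 1.97 and 23.1, and the CD34+Flt3hi arrays at 36.4 and 34.9. The next component held 22.7% and did not follow the sort. It placed CD34-Flt3- replicates 1 and 2 at 35.0 and -30.5, those of CD34+Flt3- at -0.51 and -31.2, and those of CD34+Flt3hi at 15.1 and 12.1. Some control readings, but not all, moved with the CD34-Flt3- group. The bacterial bioC spike read 5550 and 7594 on its arrays and between 2594 and 3884 on the others, and the 3 prime actin probe set read 7693 and 7368 against 12426 to 12963. The 3 prime over 5 prime ratio of Gapdh was 5.04 and 6.34 on the CD34-Flt3- arrays and 6.59 to 8.42 on the others, while the actin ratios overlapped. Readings of the 3 prime Gapdh probe set (7277 and 6530 against 6918 to 7671) and of the cre spike (18405 and 19228 against 17774 to 19093) overlapped as well.

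Mean Cd34 and Flt3 RNA rose in the order of the sort, from levels well above background in the groups sorted as negative. Cd34 (Entrez gene 12490) was 9.12 ± 0.48 (SD, n = 2) in CD34-Flt3- cells, 10.60 ± 0.12 in CD34+Flt3- cells and 11.35 ± 0.01 in CD34+Flt3hi cells. Its log2 difference was 1.48 ± 0.24 (SE, adjusted p = 0.0194, code A 1.23) at the first of these steps and 0.75 (adjusted p = 0.395, and 0.0115 with the title code as a fixed block) at the next. Flt3 (Entrez gene 14255), which encodes a cytokine receptor of early progenitors, was 8.41 ± 1.07, 9.32 ± 0.68 and 11.88 ± 0.19 in the same order. Its difference between CD34+Flt3- and CD34-Flt3- cells, 0.92 ± 0.45 (SE), did not pass (limma adjusted p = 0.34). The arrays of these groups overlapped (8.84 and 9.81 against 7.65 and 9.16). Flt3 was 2.56 ± 0.45 higher on the log2 scale in CD34+Flt3hi than in CD34+Flt3- cells (adjusted p = 0.0444; 1.94 in code A and 3.17 in code B). CD34+Flt3hi cells exceeded CD34-Flt3- cells by 2.23 ± 0.24 for Cd34 (adjusted p = 0.000869, code A 1.89) and by 3.48 ± 0.45 for Flt3 (adjusted p = 0.00215, code A 2.59). Kit, the stem cell factor receptor, gave log2 differences of -0.87, -0.12 and -0.98 for the 3 comparisons, none past the threshold (adjusted p = 0.385, 0.992 and 0.309). Ly6a, which encodes Sca1, had no probe set naming it alone and was not analysed here. The adjusted p of Cd34 at the first step was 0.0668 without CD34+Flt3- replicate 1, 0.241 without its replicate 2, 0.0642 and 0.0665 without CD34+Flt3hi replicates 1 and 2, and 0.0714 in a fit of the 4 arrays compared. The adjusted p of Flt3 at the next step was 0.423 and 0.0998 without CD34+Flt3- replicates 1 and 2, 0.374 and 0.269 without CD34+Flt3hi replicates 1 and 2, and 0.0555 to 0.0977 with 4 other settings of the fit or the probe sets.

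The first comparison asked what differs between CD34+Flt3- and CD34-Flt3- cells, which share the absence of high Flt3. By limma over all genes, 18 of 34 G2 and M phase genes and 6 of 26 granulocyte and monocyte genes were higher in CD34+Flt3- cells, while 23 of 38 stem-cell-associated and 4 of 28 megakaryocyte and erythroid genes were lower. As lists none of these passed camera with an estimated correlation (adjusted p = 0.3 for the first 3 and 0.717 for the last). Cep55, which acts in the last step of cell division, was 11.6-fold higher (log2 3.54 ± 0.28, SE, n = 2; adjusted p = 0.00403; Entrez gene 74107). Mpo, the peroxidase of neutrophil granules, was 7.13-fold higher (log2 2.83 ± 0.27, adjusted p = 0.00456, Entrez gene 17523). Hoxb5, a homeobox gene used as a marker of long-term stem cells, was 9.15-fold lower (log2 -3.19 ± 0.30, adjusted p = 0.00456, Entrez gene 15413), and Vwf, von Willebrand factor, was 16.7-fold lower (log2 -4.06 ± 0.67, adjusted p = 0.0197, Entrez gene 22371). Vwf read 8.25 and 5.53 on CD34+Flt3- replicates 1 and 2, and its difference was -5.42 without replicate 1 and -2.70 without replicate 2.

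Other genes with the largest rises were Nuf2 (log2 3.16), Cenpf (2.94) and Nusap1 (2.89), which serve the kinetochore and spindle, Ube2c (2.84), which serves the ubiquitin ligase of anaphase, the granule protease gene Ctsg (3.01) and Tcf19 (2.80). The 2 CD34-Flt3- arrays differed in some of these, with an SD of 1.91 for Nuf2, 1.75 for Nusap1, 1.55 for Ube2c and 1.16 for Cenpf. Without CD34-Flt3- replicate 2 the rises were 1.80 for Nuf2, 1.65 for Nusap1, 1.74 for Ube2c and 2.12 for Cenpf. Without replicate 1 they were 4.12 for Nusap1, 3.94 for Ube2c and 3.77 for Cenpf, and Nuf2 lay below background on the array that was left. Other probe sets changed less, by 0.66 for Cep55, 0.03 to 0.93 for Cenpf, and 0.53 for Nusap1 and for Tcf19. The largest falls included the erythroid carbonic anhydrase gene Car1 (log2 -4.91 ± 0.73), the erythroid membrane protein gene Ermap (-3.58 ± 0.71), the guanine deaminase gene Gda (-4.07), the sulfotransferase gene Sult1a1 (-3.68), the myosin chaperone gene Unc45b (-3.39) and the actin-bundling gene Fscn1 (-3.29). Car1 and Ermap differed widely between the 2 CD34-Flt3- arrays, with an SD of 1.98 and 2.06, and fell by 6.31 and 5.03 without replicate 2 and by 3.52 and 2.12 without replicate 1. Other probe sets differed by -0.79 to -0.03 for Fscn1 and by -2.75 to -0.68 for Gda. The naming rule, which took only genes whose arrays did not overlap, fixed that all 16 of these genes changed the same way in code A. Their changes there were 3.0 (Mpo) to 4.09 (Nusap1) for the rises and -2.29 (Ermap) to -5.25 (Vwf) for the falls, leaving aside Nuf2 and Hoxb5, each below background on 1 of the 2 arrays.

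Of 38 measured stem-cell-associated genes, 23 fell and 0 rose in CD34+Flt3- cells (31 fell when adjusted over the list alone). Their median log2 difference was -1.77 (-1.90 in code A; camera adjusted p = 8.06e-23; adjusted p = 0.3 with an estimated correlation). Hoxb5, the cell cycle inhibitor gene Cdkn1c (6.01-fold lower), the cation channel gene Trpc6 (6.0-fold lower) and Sult1a1 (12.8-fold lower) had the smallest adjusted p among them. The mean score of this list, relative to all 6 arrays, was 1.59 and 1.33 on the CD34-Flt3- arrays and 0.16 and -0.52 on CD34+Flt3- replicates 1 and 2. Of 28 megakaryocyte and erythroid genes, 4 fell (Car1, Ermap, the transcription factor gene Gfi1b at -1.27 and the water channel gene Aqp1 at -2.04), 8 when adjusted over the list alone. The median was -0.27 (-0.57 in code A; camera adjusted p = 0.0108; adjusted p = 0.717 with an estimated correlation). The scores were 1.12 and 0.60 on the CD34-Flt3- arrays and 0.43 and -0.15 on the CD34+Flt3- arrays. The mean difference of the list was -0.72 with all arrays, -1.0 without CD34+Flt3- replicate 1 and -0.43 without its replicate 2, where the camera call was lost, as it was without CD34-Flt3- replicate 1.

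All 34 measured G2 and M phase genes were higher in CD34+Flt3- cells, 18 of them past the threshold over all genes and 34 when adjusted over the list alone. The median was 2.02 (2.87 in code A; camera adjusted p = 9.27e-41; adjusted p = 0.3 with an estimated correlation). Ect2, at background in CD34-Flt3- cells, was at least 4.29-fold, Hmmr 5.52-fold (its other probe sets 0.27 to 2.51 on the log2 scale), Hmgb2 2.32-fold and Cdc20 3.55-fold higher. The 2 CD34-Flt3- arrays stood apart in this list, with scores of -0.72 for replicate 1 and -2.32 for replicate 2, against 0.50 and 0.68 on the CD34+Flt3- arrays. The mean difference of the list was 2.11 with all arrays, 1.30 without CD34-Flt3- replicate 2 and 2.91 without its replicate 1. Of 31 S phase genes, 6 rose, among them Tk1 (3.80-fold), Uhrf1 (2.94-fold), Pola1 (3.70-fold, its other probe set -0.24 on the log2 scale) and Pold1 (2.25-fold), and 21 did when adjusted over the list alone. Their median was 0.79 (0.90 in code A; camera adjusted p = 6.64e-20; adjusted p = 0.3 with an estimated correlation). Among 24 cell cycle inhibitor, D cyclin and related genes, Cdkn1c and Ccnd2 (log2 -0.94) fell while Cdkn2c (2.17) and Cdk6 (1.05) rose, with 2 rising and 7 falling when adjusted over the list alone. This list did not pass (median -0.51, -0.46 in code A, camera adjusted p = 0.168).

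Of 26 granulocyte and monocyte genes, 6 rose and 0 fell, 10 when adjusted over the list alone. Mpo, Ctsg (8.08-fold), the granule gene Nkg7 (4.45-fold) and the myeloid progenitor gene Ms4a3 (3.81-fold) led them. Their median was 0.71 (0.73 in code A; camera adjusted p = 7.06e-15; adjusted p = 0.3 with an estimated correlation). Of 25 lymphoid genes, Satb1, a chromatin organiser gene, rose 2.77-fold and Ltb, the lymphotoxin beta gene, was 2.61-fold lower. The 4 other probe sets of Satb1 ran from -0.54 to 0.48 on the log2 scale. Adjusted over the list alone, 1 lymphoid gene rose and 2 fell, and the list did not pass (median -0.26, -0.09 in code A, camera adjusted p = 0.398).

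Over all genes, 382 passed an adjusted p of 0.05, 140 higher and 242 lower in CD34+Flt3- cells, and 365 of them changed at least 2-fold. The arrays of the groups did not overlap in any of the 382 genes, as in 44.2% of all genes, where chance gives 33.3%. With quantile normalization repeated, 253 genes were higher and 245 lower, and the median of all genes was -0.03 in place of -0.10. Of 228 called genes with several probe sets, 75 had a probe set of the opposite sign, 0 of these past the threshold. Because the fixed block of title codes fits CD34-Flt3- replicate 1 exactly, its counts here rest on replicate 2 alone for that group and are no separate support. With the title code as a fixed block, 1579 genes passed (519 higher, 1060 lower), 370 of the 382 among them, and with code A against the other codes, a setting chosen after seeing the data, 1112 passed. The count was 0 without CD34+Flt3- replicate 2 (limma; 1569 genes at an unadjusted p under 0.05), 83 without its replicate 1, 45 and 48 without CD34+Flt3hi replicates 1 and 2, 892 and 983 without CD34-Flt3- replicates 1 and 2, 47 with only the 4 arrays compared, and 199 with the mean of all probe sets.

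**Figure D1:**
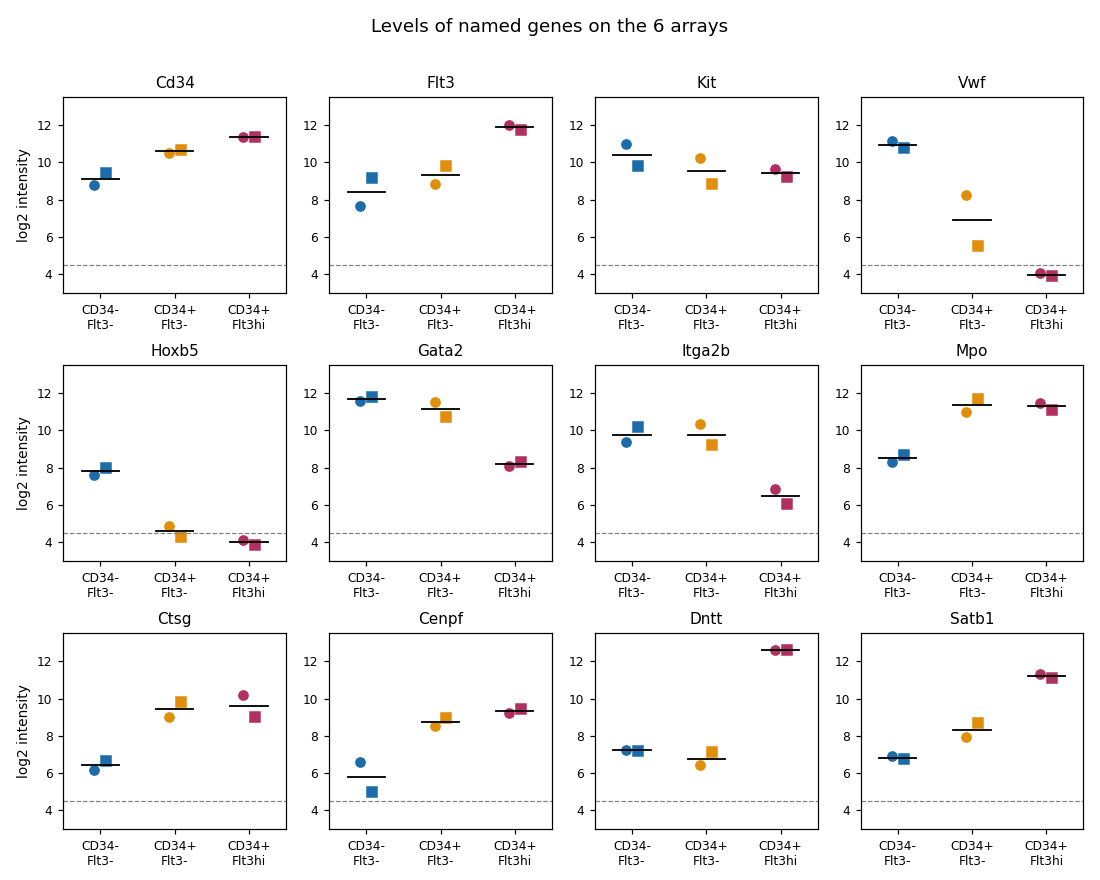
Log2 intensity (y axis) of 12 genes on each of the 6 arrays, by group on the x axis, with circles for replicate 1, squares for replicate 2, a black line for the group mean and a dashed line for background at 4.50. Dntt lies at 12.60 in CD34+Flt3hi cells and 6.78 in CD34+Flt3- cells, and Vwf goes from 10.95 in CD34-Flt3- cells to 3.98, below background, in CD34+Flt3hi cells.

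The next comparison asked what differs between CD34+Flt3hi and CD34+Flt3- cells. By limma over all genes, 4 of 25 lymphoid genes were higher in CD34+Flt3hi cells, while 6 of 28 megakaryocyte and erythroid and 6 of 38 stem-cell-associated genes were lower. As lists none of these passed camera with an estimated correlation (adjusted p = 0.199, 0.3 and 0.3). Dntt, the terminal transferase that adds nucleotides at immune receptor joints, was 56.5-fold higher (log2 5.82 ± 0.27, SE, n = 2; adjusted p = 2.28e-05; 5.49 in code A and 6.15 in code B; Entrez gene 21673). Irf8, a transcription factor gene of monocytes, dendritic cells and B cells, was 11.3-fold higher (log2 3.49 ± 0.37, adjusted p = 0.00272). Itga2b, which encodes the platelet integrin CD41, was 9.90-fold lower (log2 -3.31 ± 0.43, adjusted p = 0.00874), and Apoe, the apolipoprotein E gene, was 22.7-fold lower (log2 -4.51 ± 0.35, adjusted p = 0.00129).

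The other large rises were in the calponin gene Cnn3 (log2 4.22), the chemokine gene Ccl3 (4.10), the oxidase subunit gene Ncf1 (3.03), the membrane protein gene Emp1, the germline RNA helicase gene Ddx4 and Arpp21. The last 3 were at background in CD34+Flt3- cells, which gives rises of at least 9.04-fold for Emp1, at least 9.47-fold for Ddx4 and at least 4.07-fold for Arpp21. With only CD34+Flt3hi replicate 1, the dimmer array, these bounds are 6.64-fold, 4.89-fold and 3.37-fold. The other large falls were in the mast cell carboxypeptidase gene Cpa3 (log2 -4.05), the transglutaminase gene Tgm2 (-3.48) and 4 genes at background in CD34+Flt3hi cells. These were the monoamine transporter gene Slc18a2, at least 16.3-fold lower, the retinaldehyde dehydrogenase gene Aldh1a1, at least 10.6-fold, the adaptor gene Grb10, at least 11.6-fold, and the platelet chemokine gene Pf4, at least 8.37-fold. With only CD34+Flt3- replicate 2, the dimmer array, these bounds are 8.41-fold, 5.80-fold, 6.43-fold and 6.19-fold in the same order. Other probe sets differed by 0.12 for Emp1, -0.12 to 1.22 for Arpp21, 1.02 to 4.41 for Cnn3, -0.51 to 0.12 for Grb10 and -4.29 to -0.40 for Tgm2. The naming rule, which took only genes whose arrays did not overlap, fixed that all 16 genes changed the same way within codes A and B. Among those above background on both arrays of the code, the changes were 2.67 (Ncf1) to 5.49 (Dntt) and -2.76 (Tgm2) to -3.71 (Apoe) in code A, and 3.38 (Ncf1) to 6.15 (Dntt) and -3.49 (Itga2b) to -5.31 (Apoe) in code B.

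Of 25 lymphoid genes, 4 rose and 0 fell, and 16 rose when adjusted over the list alone. Besides Dntt these were Satb1 (7.50-fold, its other probe sets 0.34 to 3.38 on the log2 scale), the receptor gene Notch1 (6.02-fold), which directs T lineage choice, and Flt3 (5.88-fold), for which the cells had been sorted. The median was 1.01 (1.12 in code A and 0.93 in code B; camera adjusted p = 4.22e-18; adjusted p = 0.199 with an estimated correlation). Of 28 megakaryocyte and erythroid genes, 6 fell and 0 rose, 1 rising and 15 falling when adjusted over the list alone. Their median was -1.06 (-0.66 in code A and -1.48 in code B; camera adjusted p = 1.07e-21; adjusted p = 0.3 with an estimated correlation). Besides Pf4 and Itga2b, the transferrin receptor gene Tfr2 was 5.37-fold and the GATA cofactor gene Zfpm1 4.22-fold lower. Of 38 stem-cell-associated genes, 6 fell and 0 rose, 1 rising and 19 falling when adjusted over the list alone. The median was -0.83 (-0.51 in code A and -1.35 in code B; camera adjusted p = 1.18e-26; adjusted p = 0.3 with an estimated correlation). The transcription factor gene Gata2 was 7.72-fold, Pdzk1ip1 5.43-fold, the endothelial adhesion gene Esam 5.41-fold and Tgm2 11.2-fold lower (9.82 and 8.33 on CD34+Flt3- replicates 1 and 2). CD34+Flt3- replicate 1 stood above replicate 2 in this list, with scores of 0.16 and -0.52 against -1.32 and -1.24 on the CD34+Flt3hi arrays.

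Granulocyte and monocyte genes went both ways. Irf8, the adhesion gene Emb (4.24-fold) and the macrophage receptor gene Csf1r (4.08-fold) rose, and Ms4a3 was 5.35-fold lower, with 9 rising and 2 falling of 26 when adjusted over the list alone. The list's median was 0.50 (0.18 in code A and 0.72 in code B; camera adjusted p = 0.00698; adjusted p = 0.642 with an estimated correlation). In the S phase list 0 of 31 genes passed limma's threshold, over all genes or when adjusted over the list alone, and the list passed at a median of 0.25 (0.26 in code A and 0.13 in code B; camera adjusted p = 0.0488; adjusted p = 0.721 with an estimated correlation). In the G2 and M phase list 0 of 34 genes passed in the same way, at a median of 0.33 (0.32 in code A and 0.35 in code B; camera adjusted p = 0.0106; adjusted p = 0.797 with an estimated correlation). Of 37 cytokine and growth factor receptor genes 4 rose, namely Notch1, the interleukin 1 receptor gene Il1r1 (5.28-fold, its other probe set -0.01 on the log2 scale), Flt3, for which the cells had been sorted, and Csf1r, with 9 rising and 3 falling when adjusted over the list alone. The median was 0.18 (0.36 in code A and 0.18 in code B; camera adjusted p = 0.00559; adjusted p = 0.3 with an estimated correlation). Among 9 MHC class II genes H2-Ob rose 4.09-fold, 2 rising when adjusted over the list alone, with a median of 0.60 (0.73 in code A and 0.43 in code B; camera adjusted p = 0.000138; adjusted p = 0.3 with an estimated correlation). Of these lists, the camera calls were lost without CD34+Flt3- replicate 1 or CD34+Flt3hi replicate 1 for granulocyte and monocyte genes, without any 1 array of the groups compared for S phase, without CD34+Flt3- replicate 1 or CD34+Flt3hi replicate 2 for G2 and M phase, and without CD34+Flt3- replicate 2 for receptor genes.

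Over all genes, 111 passed, 70 higher and 41 lower in CD34+Flt3hi cells, 110 of them by at least 2-fold. The arrays of the groups overlapped in 0 of the 111. They did not overlap in 40.4% of all genes either, where chance gives 33.3%. With quantile normalization repeated, 63 were higher and 71 lower. Of 58 called genes with several probe sets, 14 had a probe set of the opposite sign, 0 of these past the threshold. With the title code as a fixed block 670 genes passed (444 higher, 226 lower), all 111 among them, with code A against the other codes 274, with array weights 293, with only the 4 arrays compared 300 and with the mean of all probe sets 69. The count was 18 and 56 without CD34+Flt3- replicates 1 and 2, 22 and 19 without CD34+Flt3hi replicates 1 and 2, and 300 and 290 without CD34-Flt3- replicates 1 and 2.

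The comparison of CD34+Flt3hi with CD34-Flt3- cells spans both gates and shares its arrays with the comparisons above. By limma over all genes, 8 of 25 lymphoid, 16 of 26 granulocyte and monocyte, 18 of 31 S phase and 33 of 34 G2 and M phase genes were higher in CD34+Flt3hi cells, while 33 of 38 stem-cell-associated, 17 of 28 megakaryocyte and erythroid and 1 of the lymphoid genes were lower. As lists none of these passed camera with an estimated correlation (adjusted p = 0.3 for each). Dntt was 41.2-fold higher (log2 5.37 ± 0.27, SE, n = 2; adjusted p = 5e-05; code A 5.40) and Satb1 20.8-fold higher (log2 4.38 ± 0.29, adjusted p = 0.000106, code A 4.34). Vwf fell from 10.95 ± 0.24 (SD, n = 2) to background, at least 87.5-fold lower (adjusted p = 0.00052). Tgm2 was 66.5-fold lower (log2 -6.06 ± 0.41, adjusted p = 0.000112, code A -5.96).

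Large rises were also found in Ccl3 (log2 5.12), the activation antigen gene Cd69 (4.65), Bex6 (4.60), the choline dehydrogenase gene Chdh (4.16), the flippase gene Atp8b4 (3.92) and Ddx4, which was at background in CD34-Flt3- cells and rose at least 9.47-fold (4.89-fold with CD34+Flt3hi replicate 1 alone). Large falls were also found in Car1 (log2 -5.97), Apoe (-5.40) and 4 genes at background in CD34+Flt3hi cells. These were Aldh1a1, at least 52.4-fold lower, Grb10, at least 42.4-fold, the caveola gene Cavin2, at least 30.2-fold, and Slc18a2, at least 26.5-fold (17.3-fold with CD34-Flt3- replicate 2 alone). Other probe sets differed by 0.15 to 3.86 for Satb1, 0.43 for Atp8b4, -6.64 to -0.60 for Tgm2, -2.22 to -1.96 for Cavin2 and -0.03 to 0.02 for Grb10. Car1 fell by 7.37 without CD34-Flt3- replicate 2 and by 4.58 without its replicate 1. The naming rule also fixed that the 16 genes changed the same way within code A. Those above background on both arrays changed by 3.42 (Atp8b4) to 5.40 (Dntt) and by -4.65 (Car1) to -5.96 (Tgm2).

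Of 38 stem-cell-associated genes, 33 fell and 0 rose, with 1 rising and 35 falling when adjusted over the list alone. The median was -2.81 (-2.46 in code A; -2.77 with values below background set to it; camera adjusted p = 2.74e-37; adjusted p = 0.3 with an estimated correlation). Pdzk1ip1 was 18.7-fold lower, Trpc6 at least 11.8-fold and Cdkn1c at least 9.58-fold. Of 28 megakaryocyte and erythroid genes, 17 fell and 0 rose, 22 when adjusted over the list alone, and all 28 differences were negative. The median was -1.46 (-1.38 in code A; camera adjusted p = 5.32e-17; adjusted p = 0.3 with an estimated correlation). Gfi1b was 6.42-fold, Tfr2 6.70-fold, Zfpm1 5.68-fold and Aqp1 at least 15.4-fold lower.

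Of 34 G2 and M phase genes, 33 rose, 34 when adjusted over the list alone, with a median of 2.40 (3.23 in code A; camera adjusted p = 3.66e-38; adjusted p = 0.3 with an estimated correlation). The mean difference of the list was 2.45 with all arrays, 1.65 without CD34-Flt3- replicate 2 and 3.25 without its replicate 1. Cenpf, which read 6.61 and 4.97 on CD34-Flt3- replicates 1 and 2, was 11.7-fold, Ect2 at least 9.13-fold, Hmmr 5.80-fold and Hmgb2 2.88-fold higher. Of 31 S phase genes, 18 rose and 0 fell, 25 rising and 1 falling when adjusted over the list alone, with a median of 1.0 (1.33 in code A; camera adjusted p = 2.57e-20; adjusted p = 0.3 with an estimated correlation). Pola1 was 4.22-fold, Tk1 3.57-fold, Prim1 3.06-fold and Uhrf1 2.98-fold higher, while other probe sets of Hmmr differed by 0.04 to 2.99 and that of Pola1 by -0.27. Of 26 granulocyte and monocyte genes, 16 rose and 0 fell, 18 when adjusted over the list alone. The median was 1.37 (0.99 in code A; camera adjusted p = 2.38e-15; adjusted p = 0.3 with an estimated correlation). Irf8 was 14.6-fold, Cst7 13.8-fold, Mpo 6.88-fold and Plac8 3.05-fold higher. Of 25 lymphoid genes, 8 rose and 1 fell, 10 and 1 when adjusted over the list alone. Flt3 was 11.1-fold and Notch1 3.69-fold higher besides Dntt and Satb1, and the median was 0.56 (0.80 in code A; camera adjusted p = 3.35e-07; adjusted p = 0.3 with an estimated correlation).

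Over all genes, 1112 passed, 476 higher and 636 lower in CD34+Flt3hi cells, 1021 of them by at least 2-fold. The arrays of the groups overlapped in 0 of the 1112. They did not overlap in 47.9% of all genes either, where chance gives 33.3%. Of 641 called genes with several probe sets, 188 had a probe set of the opposite sign and 1 of these passed the threshold. Here too the fixed block of title codes uses CD34-Flt3- replicate 2 alone for that group. With the title code as a fixed block 2360 genes passed (986 higher, 1374 lower), 1060 of the 1112 among them, and with code A against the other codes 1710. The count was 294 and 271 without CD34+Flt3hi replicates 1 and 2 and 1918 without CD34-Flt3- replicate 1.

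**Figure D2:**
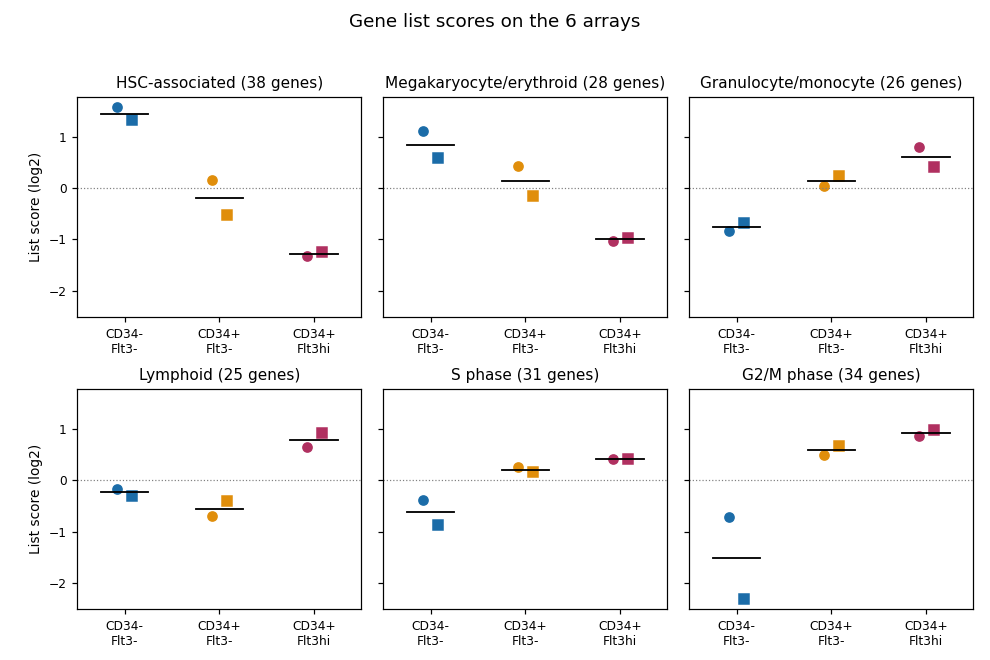
Score of 6 gene lists (y axis, mean over the list of the log2 intensity minus the gene's mean over the 6 arrays) on each array, by group on the x axis, with circles for replicate 1 and squares for replicate 2. The stem-cell-associated score goes from 1.59 and 1.33 in CD34-Flt3- cells to -1.32 and -1.24 in CD34+Flt3hi cells, and the G2 and M phase score lies at -0.72 and -2.32 in CD34-Flt3- cells and between 0.50 and 0.98 in the others.

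Whether a gene changed by different amounts at the step to CD34 and at the step to high Flt3 was tested as the difference of these steps. It passed for 5 genes, named here because of their small number: Dntt, the lysosomal protease gene Ctss, the tropomyosin gene Tpm4, Cpa3 and Ms4a3. The step to high Flt3 exceeded the step to CD34 by 6.27 on the log2 scale for Dntt (adjusted p = 0.00211), 4.13 for Ctss (adjusted p = 0.0146) and 3.87 for Tpm4 (adjusted p = 0.0229). The difference was -5.05 for Cpa3 (adjusted p = 0.0303) and -4.35 for Ms4a3 (adjusted p = 0.0229). Ms4a3 was 5.49 in CD34-Flt3- cells, 7.42 in CD34+Flt3- cells and 5.0 in CD34+Flt3hi cells, and Ctss was 9.08, 7.81 and 10.68. The count was 560 with the title code as a fixed block, 71 with code A against the other codes, 8 with array weights and 13 with all probe sets tested singly. It was 118 and 91 without CD34-Flt3- replicates 1 and 2, 1 and 3 without CD34+Flt3- replicates 1 and 2, and 2 and 1 without CD34+Flt3hi replicates 1 and 2. Any difference among the 3 groups, by limma's moderated F, was found for 849 genes. That count was 2428 with the fixed block, 1646 with code A against the other codes, 1309 at an adjusted p under 0.10, 1501 and 1343 without CD34-Flt3- replicates 1 and 2, 483 without CD34+Flt3- replicate 2, and 240 and 241 without CD34+Flt3hi replicates 1 and 2.

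Markers of cells outside the LSK gate were measured in 8 lists. Endothelial genes were lower in CD34+Flt3- than in CD34-Flt3- cells, where Kdr was 2.67-fold lower and 1 of 21 fell (8 when adjusted over the list alone). The median was -0.18 (-0.30 in code A; camera adjusted p = 0.0322; adjusted p = 0.3 with an estimated correlation), and the camera call was lost without CD34-Flt3- replicate 2 or CD34+Flt3- replicate 1. In CD34+Flt3hi against CD34-Flt3- cells 6 of 21 fell, among them Tie1 (7.24-fold), Kdr (3.46-fold), Mmrn1 (9.43-fold) and Sox18 (2.67-fold; the other probe set of Mmrn1 differed by -0.25), with 1 rising and 9 falling when adjusted over the list alone. The median was -0.26 (-0.43 in code A; camera adjusted p = 0.0122; adjusted p = 0.3 with an estimated correlation). These falls went with those of the stem-cell-associated list, and 2 of the 21 genes are on another list here. Between CD34+Flt3hi and CD34+Flt3- cells Tie1 was 4.35-fold lower and the list did not pass (median -0.02, camera adjusted p = 0.244).

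Mast cell, basophil and eosinophil genes were lower in CD34+Flt3hi than in CD34+Flt3- cells, by Cpa3 and the IgE receptor gene Ms4a2, 2 of 15 genes (3 when adjusted over the list alone). Ms4a2 was at background in CD34+Flt3hi cells and at least 2.15-fold lower (1.37-fold with CD34+Flt3- replicate 2 alone), while its other probe set differed by 0.24 on the log2 scale. The median was -0.18 (-0.11 in code A and -0.36 in code B; camera adjusted p = 0.000207; adjusted p = 0.3 with an estimated correlation). With values below background set to it, that median was -0.09. The list did not pass against CD34-Flt3- cells, for CD34+Flt3- (median 0.14, camera adjusted p = 0.0702) or CD34+Flt3hi cells (median -0.10, camera adjusted p = 0.36). In CD34+Flt3- cells Ms4a2 was at least 2.15-fold higher, from background (1.37-fold with replicate 2 alone), and the interleukin 4 gene Il4 was lower (log2 -1.39). In CD34+Flt3hi cells Cpa3 (log2 -3.04), Il4, at least 2.65-fold, and Gata1, at least 3.97-fold (2.14-fold with CD34-Flt3- replicate 2 alone), were lower. Dendritic cell genes passed between CD34+Flt3hi and CD34+Flt3- cells at a median of 0.16 (0.04 in code A and 0.23 in code B; camera adjusted p = 0.0214; adjusted p = 0.3 with an estimated correlation). The member that rose was Flt3, 1 of 13 (3 when adjusted over the list alone), and the camera call was lost without CD34+Flt3- replicate 1. These groups had been sorted by Flt3, so its rise was set by the gate. The list did not pass against CD34-Flt3- cells, for CD34+Flt3- (median -0.13, an upward test, camera adjusted p = 0.996) or CD34+Flt3hi cells (median 0.20, camera adjusted p = 0.143). The protease gene Ctsl was 3.39-fold and 3.03-fold lower in these, and in CD34+Flt3hi cells Flt3 was 11.1-fold and the chemokine receptor gene Ccr9 at least 2.37-fold higher, from background (1.14-fold with CD34+Flt3hi replicate 1 alone). Stromal and bone lineage genes passed between CD34+Flt3hi and CD34+Flt3- cells at a median of -0.15 (-0.27 in code A and -0.03 in code B; camera adjusted p = 0.0495; adjusted p = 0.668 with an estimated correlation), where the proteoglycan gene Bgn, 1 of 20, was 6.39-fold lower (1 when adjusted over the list alone), and the camera call was lost in 4 of the 6 runs without a single array. With values below background set to it, the median of the stromal and bone lineage list there was -0.02. The list did not pass against CD34-Flt3- cells, for CD34+Flt3- (median 0.09, camera adjusted p = 0.228) or CD34+Flt3hi cells (median -0.13, camera adjusted p = 0.954). Pdgfrb was 3.07-fold and 4.49-fold higher in these, and in CD34+Flt3hi cells Bgn was 11.3-fold and the collagen gene Col1a2 3.14-fold lower.

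Mature erythroid, neutrophil and monocyte, B lineage, and T and NK lineage lists passed in none of the 3 comparisons with camera. In the order of the comparisons given here, the medians of 9 erythroid genes were -0.28, 0.02 and -0.14 (adjusted p = 0.508, 0.887 and 0.657). Those of 25 neutrophil and monocyte genes were 0.03, 0.00 and 0.04 (adjusted p = 0.154, 0.308 and 0.524), the middle test pointing down with a mean of -0.04. Those of 19 B lineage genes were -0.41, 0.08 and -0.15 (adjusted p = 0.37, 0.555 and 0.733). Those of 22 T and NK genes were 0.04, -0.02 and -0.19 (adjusted p = 0.41, 0.163 and 0.79), and Thy1 was 3.0-fold lower in CD34+Flt3hi than in CD34+Flt3- cells. In CD34+Flt3hi against CD34-Flt3- cells Bpgm of the erythroid list was 2.33-fold lower and Thy1 2.89-fold, and Bcl11b of the T and NK list was at least 3.59-fold lower. Pou2af1 of the B lineage list passed as lower (log2 -1.01), with the means of both groups, 4.12 in CD34-Flt3- and 3.11 in CD34+Flt3hi cells, below background.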

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

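All tests of explanations in this part were chosen only after the results they bear on were seen, while the differences of the steps and the tests of probe sets without a gene name use the planned fit. Groups of 2 arrays are too small for a test of single arrays far from their group, and 2 against 2 arrays can be split in too few other ways to count splits.

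The step from CD34+Flt3- to CD34+Flt3hi cells differed from the step from CD34-Flt3- to CD34+Flt3- cells, by limma's test of the difference, for 5 genes. The difference on the log2 scale was 6.27 for Dntt, 4.13 for Ctss, 3.87 for Tpm4, -5.05 for Cpa3 and -4.35 for Ms4a3. Cpa3 was 7.58 in CD34-Flt3-, 8.59 in CD34+Flt3- and 4.54 in CD34+Flt3hi cells, and Tpm4 was 7.50, 6.57 and 9.52.

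Probe sets without a gene name, which the comparisons of genes do not use, also differed between groups. Of 9160 such probe sets, 29 passed between CD34+Flt3- and CD34-Flt3- cells (15 higher, 14 lower), 14 between CD34+Flt3hi and CD34+Flt3- cells (11 higher, 3 lower) and 157 between CD34+Flt3hi and CD34-Flt3- cells (99 higher, 58 lower), by limma with all probe sets adjusted together. The probe set with the largest difference read 8.52 in CD34+Flt3hi cells and lay below background in CD34+Flt3- and CD34-Flt3- cells, at least 16.2-fold lower in each (adjusted p = 0.000236 and 0.000132).

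G2 and M phase genes were lower in CD34-Flt3- than in CD34+Flt3- cells, with a median difference of 2.02 between these groups. A change shared by all genes of similar brightness was not seen, since 0 of 10000 random lists matched in level had a median as high. The highest 2.5% of them began at -0.064. The array medians were alike after RMA and the list was known to be higher, so this test could hardly have come out otherwise. It does not bear on a change that affects some transcripts more than others. Loss of 5 prime signal on the CD34-Flt3- arrays would raise their 3 prime over 5 prime ratios. Their Gapdh ratios of 5.04 and 6.34 pointed the other way, below 6.83, the lowest on the CD34+Flt3- arrays. They differ from each other by more than the gap up to it, however. The highest actin ratio, 5.55, was on CD34-Flt3- replicate 2, which had the lowest G2 and M score (-2.32). Such a loss was therefore not seen in Gapdh, but with actin it cannot be told apart from the group. A smaller share of cycling cells among CD34-Flt3- cells stays open beside it as a hypothesis, as the S phase list was higher in CD34+Flt3- cells as well (median 0.79, where the highest 2.5% of its matched lists began at -0.026). The size of the difference stays open, because all 34 genes were lower in CD34-Flt3- replicate 2 than in replicate 1 (median -1.76), while the corresponding medians were 0.16 and 0.08 in the other groups.

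Of the 1112 genes that passed between CD34+Flt3hi and CD34-Flt3- cells, 963 had a CD34+Flt3- mean between those of the other groups, as 39.7% of all genes did, and choosing genes by the outer groups favours this. A mixture of CD34-Flt3- and CD34+Flt3hi cells in this gate could give such levels, with the same share for every gene. Over 44 genes at least 8-fold brighter in CD34-Flt3- than in CD34+Flt3hi cells the median share was 0.18. The quartiles of the log2 share differed by 1.48 against a wide bound of 1.55, which is 2.7 times the median SE of 0.57. The quartiles stayed within that bound, but 10 of the 44 genes lay over 3 SE from the median share, more than 1 common share would leave. A common share was thus not borne out. These genes were chosen for their large difference and the SE rests on 2 arrays per group. A mixture therefore cannot be told apart from differences gene by gene. A mixture of only these cells would not put a level outside their range, where 5 genes passed against both groups. These were Ms4a3 and Ms4a2 above and Ctss, Esr1 and Slc49a4 below, named after their values were seen. They do not decide the question, because they were picked from all genes for this and both calls share the CD34+Flt3- arrays. The larger limma adjusted p was 0.0485 for Ms4a2, 0.0488 for Esr1 and 0.0496 for Slc49a4, and no number expected without a change was worked out.

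CD34+Flt3- replicate 1 lay nearer to CD34-Flt3- cells than replicate 2 did. Stem-cell-associated genes were 0.52 higher in code B for CD34+Flt3- cells (25 of 28 genes) but -0.11 apart for CD34+Flt3hi cells (11 of 28 higher). The only other pair of codes B and A thus did not show the difference. The CD34-Flt3- arrays, of codes C and A, do not compare these codes, but were 0.27 apart, with code A lower. With 1 array per code and group, a difference between codes B and A cannot be told apart from other differences between the arrays. CD34-Flt3- cells carried over into replicate 1 could raise genes bright in CD34-Flt3- cells by the same share, and 42 of the 44 genes used above were higher in replicate 1. In 31 of them, chosen as at least 4-fold lower in replicate 2 than in CD34-Flt3- cells, which favours a higher replicate 1, the median share was 0.20. The quartiles differed by 0.23 against a bound of 0.33, again 2.7 times the median SE. However, Gda, Car1, Unc45b and Sult1a1 lay over 3 SE below the median share. Carry-over cannot be told apart from other differences between the arrays, since each code has 1 array of the group, and no difference between mice was tested.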

How the results depend on the processing

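The block of title code A against the others was chosen only after the results were seen, and all other alternatives were planned. Where a count changed by over 1.5 times or a call changed, the cause was not tested, except that fewer arrays leave fewer degrees of freedom and the fixed block of title codes leaves 1. Each array left out costs the same, so this alone cannot explain counts that differ by the array left out. The spread shared by all groups changes as well, since the median SD between replicates was 0.24 in CD34-Flt3-, 0.18 in CD34+Flt3- and 0.13 in CD34+Flt3hi cells. Lone arrays of a group are assumed to vary like the other groups. Among counts, 112 values stayed within 1.5 times and 48 did not. The 4 called differences of Cd34 and Flt3 kept their direction in all 76 values and lost the call in 13. Of the values for named genes and the other sort antigens, 913 kept direction and call, 80 lost the call, 6 gained it and 2 turned. For lists called under some setting these were 696, 90, 15 and 13. Another 35 list results were called under no setting, and 54 of their 656 values changed direction, in 20 results. Signal over background limits the 26.7% of genes below a log2 of 4.50. The pairing of arrays by title code was checked by the correlation across genes of their deviations from the group mean, which was 0.31, 0.06 and 0.07 for the pairs within code A.

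For CD34+Flt3- minus CD34-Flt3-, CD34+Flt3hi minus CD34+Flt3- and CD34+Flt3hi minus CD34-Flt3- in this order, the fixed block gave 1579, 670 and 2360 genes and code A against the others gave 1112, 274 and 1710. Only the 4 arrays compared gave 47 and 300 genes for the comparisons up to CD34+Flt3hi minus CD34+Flt3-, and the mean of all probe sets gave 199 and 69. An adjusted p under 0.10 gave 843 for CD34+Flt3- minus CD34-Flt3-, and array weights gave 293 for CD34+Flt3hi minus CD34+Flt3-. The difference of the steps gave 560 with the fixed block, 71 with code A against the others, 8 with array weights and 13 with all probe sets singly, and any difference among the groups gave 2428, 1646 and, at an adjusted p under 0.10, 1309. Quantile normalization again moved the median of all genes for the difference of the steps from 0.14 to 0.03. Camera with an estimated correlation called 0, 0 and 0 lists, where 2, 4 and 6 had an unadjusted p under 0.05, and list counts without single arrays were 8 to 9, 8 to 10 and 10 to 11.

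Leaving out single arrays gave 0 (without CD34+Flt3- replicate 2; 1569 at an unadjusted limma p under 0.05) to 983 (without CD34-Flt3- replicate 2) genes for CD34+Flt3- minus CD34-Flt3-. It gave 18 (without CD34+Flt3- replicate 1) to 300 (without CD34-Flt3- replicate 1) for CD34+Flt3hi minus CD34+Flt3- and 271 (without CD34+Flt3hi replicate 2) to 1918 (without CD34-Flt3- replicate 1) for CD34+Flt3hi minus CD34-Flt3-. The difference of the steps gave 1 (without CD34+Flt3- replicate 1) to 118 (without CD34-Flt3- replicate 1), and any difference among the groups 240 (without CD34+Flt3hi replicate 1) to 1501 (without CD34-Flt3- replicate 1).

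Cd34 for CD34+Flt3- minus CD34-Flt3- lost its call at 1.48 with only the 4 arrays compared and ran from 1.14 to 1.82 without single arrays. For CD34+Flt3hi minus CD34+Flt3- it gained a call at 0.75 with the fixed block and with only the 4 arrays compared, and ran from 0.67 to 0.84 without single arrays. Flt3 for CD34+Flt3hi minus CD34+Flt3- lost its call at 2.56 without an intensity trend, with the mean of all probe sets and with all probe sets singly, at 2.38 with quantile normalization again, and in 4 of the runs without single arrays, which ran from 2.07 to 3.04. Kit, never called in that comparison, ran from -0.84 to 0.61.

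The list test turned direction in these cases, given as list means. Ribosome biogenesis and Myc target genes for CD34+Flt3- minus CD34-Flt3- gave 0.021 with the fixed block, 0.057 with quantile normalization again, -0.14 without the dim genes, -0.073 with the mean of all probe sets, and -0.32 to 0.043 without single arrays. Immediate early and stress genes gave -0.22 without the dim genes and -0.55 to 0.17 without single arrays for CD34+Flt3- minus CD34-Flt3-, 0.0075 to 0.27 for CD34+Flt3hi minus CD34+Flt3-, and -0.42 with the fixed block and -0.41 to 0.31 without single arrays for CD34+Flt3hi minus CD34-Flt3-. Interferon response genes for CD34+Flt3hi minus CD34-Flt3- gave -0.56 to -0.070 without single arrays.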

Other observations

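All tests in this part were planned, and none was chosen only after its result was seen. Among the metabolic lists, glycolysis and hypoxia genes were lower in CD34+Flt3- than in CD34-Flt3- cells, where 3 of 29 fell, the aldolase genes Aldoa (2.32-fold) and Aldoc (2.54-fold) and the phosphofructokinase gene Pfkm (2.23-fold), or 1 rising and 9 falling when adjusted over the list alone. The median was -0.43 (-0.40 in code A; camera adjusted p = 0.00559; adjusted p = 0.443 with an estimated correlation). Against CD34-Flt3- cells, CD34+Flt3hi cells had 2 higher and 6 lower, among these the glucose transporter gene Slc2a3 (3.04-fold lower), with 3 rising and 10 falling when adjusted over the list alone. The median was -0.47 (-0.26 in code A; camera adjusted p = 0.035; adjusted p = 0.576 with an estimated correlation), and the camera call was lost without CD34-Flt3- replicate 1 or CD34+Flt3hi replicate 1. Between CD34+Flt3hi and CD34+Flt3- cells the median was -0.08, the mean 0.04 and the test up (camera adjusted p = 0.977). Oxidative phosphorylation genes passed upward with 0 of 44 genes past limma's threshold in CD34+Flt3- against CD34-Flt3- cells, over all genes or when adjusted over the list alone (median 0.07, 0.12 in code A; camera adjusted p = 0.0143; adjusted p = 0.717 with an estimated correlation). This rested on CD34-Flt3- replicate 2, without which the list mean went from 0.080 to -0.039 and the call was lost, while it was 0.20 without replicate 1. In CD34+Flt3hi against CD34-Flt3- cells 5 of 44 rose, among them Cox6a1 (1.65-fold), Ndufa4 (2.78-fold), Ndufs8 (1.83-fold) and Cox5a (1.58-fold), and 6 did when adjusted over the list alone. The median was 0.13 (0.32 in code A; camera adjusted p = 0.000756; adjusted p = 0.615 with an estimated correlation), and 0.10 between CD34+Flt3hi and CD34+Flt3- cells, which did not pass (camera adjusted p = 0.104). Against CD34-Flt3- cells the list mean of CD34+Flt3hi cells was 0.20 with all arrays, 0.32 without CD34-Flt3- replicate 1 and 0.077 without its replicate 2, where the call was lost.

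Of 29 Hox genes and cofactors, 5 fell in CD34+Flt3hi against CD34-Flt3- cells, 7 when adjusted over the list alone. The median level of the list was 4.50 to 5.03 on the 6 arrays, near background. With values below background set to it, the median difference was 0 in place of -0.17, so the list as a whole did not shift. Hoxb5 was at least 9.86-fold, Pbx3 4.35-fold and Meis1 2.74-fold lower, and the median was -0.17 (-0.23 in code A; camera adjusted p = 0.0185; adjusted p = 0.417 with an estimated correlation). In CD34+Flt3- against CD34-Flt3- cells Hoxb5 and Pbx3 (2.7-fold) fell, as did Meis2, at background in CD34+Flt3- cells and at least 1.09-fold lower, and 1 rose and 7 fell when adjusted over the list alone, but the list did not pass (median -0.09, camera adjusted p = 0.183). Between CD34+Flt3hi and CD34+Flt3- cells it passed with 0 of 29 genes past limma's threshold and 1 rising when adjusted over the list alone (median -0.11, -0.14 in code A and -0.11 in code B; camera adjusted p = 0.0495; adjusted p = 0.505 with an estimated correlation). With values below background set to it, that median was -0.004. The list mean there was -0.13 with all arrays, -0.049 without CD34+Flt3- replicate 1 and -0.21 without its replicate 2. The call was lost in 5 of the 6 runs without a single array. Interferon response genes were lower in CD34+Flt3- than in CD34-Flt3- cells, where Iigp1 (4.14-fold) and Rsad2 (2.78-fold) fell, 2 of 31, or 6 when adjusted over the list alone. The median was -0.36 (-0.30 in code A; camera adjusted p = 0.0101; adjusted p = 0.721 with an estimated correlation), and the other comparisons did not pass (medians 0.09 and -0.23, camera adjusted p = 0.136 and 0.228). The scores of the interferon list were 0.51 and 0.02 on the CD34-Flt3- arrays and -0.04 and -0.41 on the CD34+Flt3- arrays. The list mean between these groups was -0.49 with all arrays, -0.25 without CD34-Flt3- replicate 1 and -0.74 without its replicate 2, and the call was lost without CD34-Flt3- replicate 1 or CD34+Flt3- replicate 2.

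Adhesion and homing genes passed in no comparison (medians -0.20, 0.03 and -0.35 in the order used above, camera adjusted p = 0.308, 0.531 and 0.163; the middle test pointed down). Cd48, which is absent from long-term stem cells, was 5.24-fold higher in CD34+Flt3- and 9.99-fold higher in CD34+Flt3hi than in CD34-Flt3- cells, and Esam was 11-fold lower in CD34+Flt3hi than in CD34-Flt3- cells. In CD34+Flt3hi against CD34-Flt3- cells 4 of 35 rose and 10 fell, 5 and 13 when adjusted over the list alone. In CD34+Flt3- against CD34-Flt3- cells 1 rose and 4 fell, 2 and 9 when adjusted over the list alone. MHC class II genes fell in part in CD34+Flt3- against CD34-Flt3- cells, by H2-Aa (3.78-fold), Cd74 (3.23-fold) and H2-Eb1 (3.01-fold), 3 of 9 genes or 2 rising and 4 falling when adjusted over the list alone, without a call of the list (median -0.01, camera adjusted p = 0.567). Between CD34+Flt3hi and CD34-Flt3- cells this list had a median of -0.22, a mean of 0.24 and an upward test (camera adjusted p = 0.308). Cytokine and growth factor receptor genes did not pass against CD34-Flt3- cells (medians -0.35 and 0.02, camera adjusted p = 0.508 and 0.325), though Il6st was 3.27-fold lower in CD34+Flt3- cells and Tgfbr3 (9.39 and 8.13 on CD34-Flt3- replicates 1 and 2) 15.4-fold lower in CD34+Flt3hi cells. Of these 37 genes 0 rose and 3 fell in CD34+Flt3- cells, 0 and 3 when adjusted over the list alone, and 6 rose and 4 fell in CD34+Flt3hi cells, 8 and 4 when adjusted over the list alone. Cell cycle inhibitor and D cyclin genes did not pass for CD34+Flt3hi cells against CD34+Flt3- or CD34-Flt3- cells (medians 0.27 and -0.17, camera adjusted p = 0.325 and 0.723).

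In the order used above, the medians of 37 cytosolic ribosomal protein genes were -0.08, 0.04 and -0.01 (camera adjusted p = 0.719, 0.37 and 0.812), the last with an upward test. Those of 39 ribosome biogenesis and Myc target genes were -0.16, 0.12 and -0.06 (camera adjusted p = 0.712, 0.308 and 0.789), the last with an upward test. Those of 37 immediate early and stress genes were -0.12, 0.07 and -0.05 (camera adjusted p = 0.567, 0.228 and 0.741), the last with an upward test, and Egr1 was 2.23-fold lower in CD34+Flt3hi than in CD34-Flt3- cells. Those of 4 sex-linked genes were -0.15, 0.16 and -0.34 (camera adjusted p = 0.719, 0.977 and 0.678), the middle test pointing down.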
